A study of Homo sapiens with 24 samples.

How the data were processed

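Total RNA of 4 multiple myeloma cell lines was sequenced after electroporation with a pool of siRNAs against IRF4 (siIRF4) and in control cells (CTRL). MM1R and MM1S are established lines from the same donor, and KMS-12-BM and KMS-12-PE are established lines from another donor. Each line had 3 siIRF4 and 3 CTRL libraries, 24 libraries in total. The labels give siIRF4 cells a time of 48 hours and CTRL cells a DMSO treatment at 0 hours, and they name no control siRNA. Knock down, delivery of siRNA as such, electroporation, DMSO and time in culture therefore differ together between siIRF4 and CTRL by the labels. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these libraries.

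The submitters' processing notes name alignment to hg19 with STAR, counting with featureCounts and quality reports with FastQC and MultiQC, with no versions. The deposited values are transcripts per M (TPM) made by the authors, 1 column per library. Each column sums to the same total over 25370 listed genes. The annotation, strandedness and gene lengths are not given in the sources used here. No mitochondrially encoded genes and no immunoglobulin gene segments are listed. A total of 28 rows whose symbols had become calendar dates and 1 row with no gene name were left out.

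Whole reads were recovered from the TPM values, since within a gene the values of the libraries are whole reads times a factor of each library. The factors found from different genes differed by at most 1.8e-09 of their size. With a tolerance of 0.02 reads and at least 6 libraries with a value, 22700 genes gave whole reads in every library. They covered at least 99.96% of each library's TPM. Recovered totals lay between 17.3 and 27.4 M reads, and were 19.3 to 22.3 M in MM1R CTRL, 21.7 to 27.4 M in MM1R siIRF4, 17.3 to 24.1 M in MM1S CTRL and 20.1 to 21.0 M in MM1S siIRF4. They were 20.9 to 23.8 M in KMS-12-BM CTRL, 18.4 to 25.3 M in KMS-12-BM siIRF4, 21.0 to 21.6 M in KMS-12-PE CTRL and 19.2 to 24.3 M in KMS-12-PE siIRF4. No pair of replicates was a copy of the same library, since the lowest chi-square per degree of freedom between replicates was 2.14.

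The tests used log2(TPM + 1) of the 15113 genes with a TPM of at least 1 in at least 3 libraries. All 24 libraries entered 1 fit of 8 group means in limma 3.58.1 with R 4.3.3, with a trended and robust prior (eBayes). Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. The comparisons were siIRF4 against CTRL in each line and on average over the 4 lines with equal weights, the differences of these effects between lines, and CTRL of related lines against each other. Log2 changes are siIRF4 minus CTRL with their SE from limma, and TPM values are means of 3 libraries. The added 1 TPM makes changes of genes near 1 TPM smaller than their ratio. Reads were recovered with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

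Gene lists were tested with camera in limma, which compares a list with all other genes, with a preset correlation of 0.01 between genes and again with a correlation estimated from the residuals. Adjusted p-values of lists are Benjamini-Hochberg values over the 35 lists tested in a comparison. The mitochondrially encoded mRNAs, fixed as a list, are not listed in the file. Beside camera, fry tested whether the genes of a list moved, on balance, one way, without comparing the list with other genes. Calls of members were also adjusted over the list alone. IRF4 itself was also tested with an exact permutation test, two-sided, whose smallest p within a line is 0.1.

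The groups, the tests, the 36 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took IRF4, then the 10 genes that rose and the 10 that fell most on average with the same sign in all 4 lines, no overlap of groups within a line and a mean of at least 5 TPM in the higher condition. It took the 5 and 5 largest changes in each line, the 3 and 3 largest differences between lines, the 5 and 5 largest differences between CTRL of related lines, and up to 2 and 2 members of each list with the smallest p. Any member of the plasma cell, IRF4-linked, pro-apoptotic and anti-apoptotic lists could be named, as could NR3C1, MAF, CCND1, CCND2, MYC, EP300 and CREBBP. RNAs without a gene name proper, such as LOC and antisense symbols, were passed over. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 TPM, median-of-ratios scaling, scaling without immunoglobulin genes, an eBayes prior without trend, a replicate block, separate fits, and each library left out in turn. Added after the data were seen were voom on the recovered reads, removal of genes open to admixture between libraries, and camera with an estimated correlation.

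The tests were tried on simulated data with the same groups and the same spread of each gene, drawn independently for each gene. Of 15113 genes, 67 changed by 0.25, 67 by 0.5 and 66 by 1. These genes were drawn only from genes of higher mean expression. In MM1R, the single line tried, 44.8% of genes with a true log2 change of 0.25 and 88.1% with 0.5 were called. There 1.94% of calls were false. For the average, 91.0% of genes with a true change of 0.25 were called, with 5.45% of calls false. For the difference between KMS-12-BM and KMS-12-PE, 71.6% with a true change of 0.5 were called, with 9.93% of calls false. Far fewer genes changed here than were called in the data. The shares therefore need not hold for the real calls, nor for genes near the filter.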

Results

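IRF4, a transcription factor that myeloma cells depend on, was knocked down in 4 myeloma cell lines to find the genes that follow its loss, in a study whose title concerns the acetyltransferase p300. Expression was measured by RNA sequencing as TPM in 3 siIRF4 and 3 CTRL libraries of each line. Recovered totals were between 17.3 and 27.4 M reads per library. The 2 leading principal components, which separated the MM1 from the KMS-12 lines and KMS-12-BM from KMS-12-PE, held 61.4% and 26.3% of the variance. Replicates of a group correlated across genes at r between 0.993 and 0.996, genes not being independent replicates.

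IRF4 transcripts fell in every line, and least in MM1R. In MM1R the mean went from 380.3 ± 17.3 to 291 ± 27.8 TPM (mean ± SD, n = 3), a loss of 23.5%. The loss was 50.4% in MM1S, 38.4% in KMS-12-BM and 52.6% in KMS-12-PE. On the log2 scale IRF4 changed by -0.39 ± 0.067 in MM1R, -1.01 ± 0.067 in MM1S, -0.70 ± 0.067 in KMS-12-BM and -1.07 ± 0.067 in KMS-12-PE (SE), with limma adjusted p = 5.8e-05, 1.1e-10, 1.8e-07 and 5.6e-11. In each line all 3 siIRF4 libraries lay below all 3 CTRL libraries, and the exact permutation p was 0.10, the smallest that 3 against 3 allow. Permuted within lines over all 24 libraries, the exact p was 1.25e-05, also the smallest possible.

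**Figure D1:**
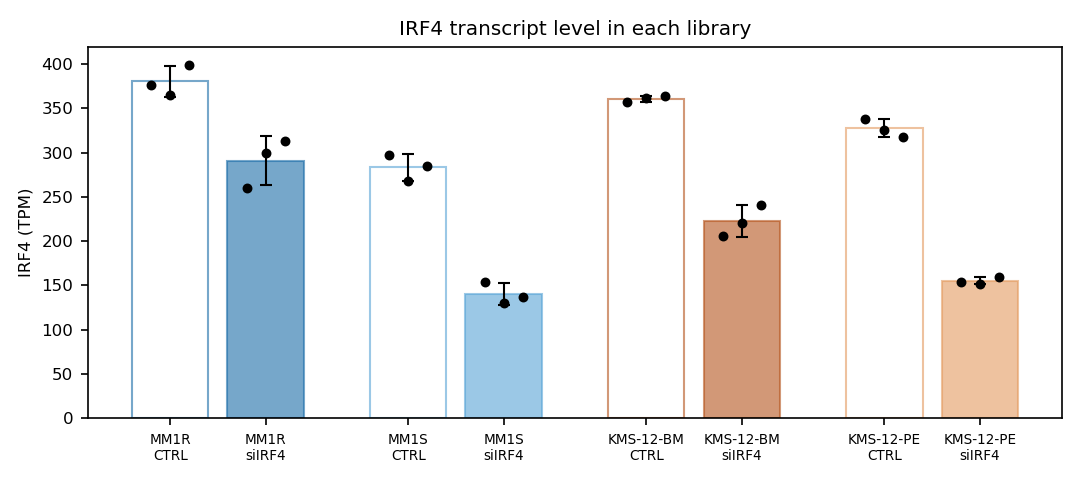
IRF4 transcript level (TPM, vertical axis) in each group, as the mean (bar), SD (whisker) and the 3 libraries (points). The siIRF4 means are 291, 141, 222 and 155 TPM in MM1R, MM1S, KMS-12-BM and KMS-12-PE.

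Averaged over the 4 lines, siIRF4 raised interferon-stimulated genes (27 of 31, adjusted p = 3.9e-08, and adjusted p = 0.0461 with an estimated correlation) and lowered single genes of plasma cells. TNFRSF17, which encodes the plasma cell survival receptor BCMA, fell by 1.71 ± 0.032 on the log2 scale, and in KMS-12-PE it went from 193 to 19.3 TPM. The chemokine gene CCL3 changed by -1.82 ± 0.11, from 1526 to 444 TPM in MM1R. KLF2, a transcription factor of B cells, changed by -1.65 ± 0.073, and POU2AF1, a B cell coactivator, by -0.84 ± 0.030. The caveolin genes CAV1 (-1.29) and CAV2 (-1.33), AMPD1 (-1.55), UNC13C (-0.84) and INSIG1 (-0.79), a regulator of sterol synthesis, completed, with IRF4 (-0.79), the 10 largest falls among genes of the same sign in all 4 lines and with no overlap between groups. Among the 10 largest rises by the same rule were LTB (1.46 ± 0.048), encoding lymphotoxin beta, and the interferon-induced genes IFITM1 (1.35 ± 0.088), PARP12 (1.27 ± 0.040) and UBE2L6 (1.24 ± 0.045).

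BMF, a pro-apoptotic member of the BCL2 family, rose by 1.29 ± 0.048 and went from 52.4 to 152 TPM in MM1R, from 41.6 to 157 TPM in MM1S and from 3.07 to 10.6 TPM in KMS-12-PE. In KMS-12-BM its change was 0.26 ± 0.096 (adjusted p = 0.0696). The other large rises were NUB1 (1.15), which had a similar change in each line (1.02 to 1.26), PVRIG (1.18), DOK7 (from 0.163 to 3.15 TPM in KMS-12-PE), FBP1 (1.16), a gluconeogenic enzyme, and TBC1D10C (1.14). In total 9014 of 15113 genes changed on average, 5005 higher and 4009 lower, but 50 of them by 1 or more on the log2 scale. siIRF4 and CTRL also differ in delivery of siRNA as such, electroporation, DMSO and time by the labels. These calls, the interferon-stimulated genes among them, therefore belong to the treatment as a whole.

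**Figure D2:**
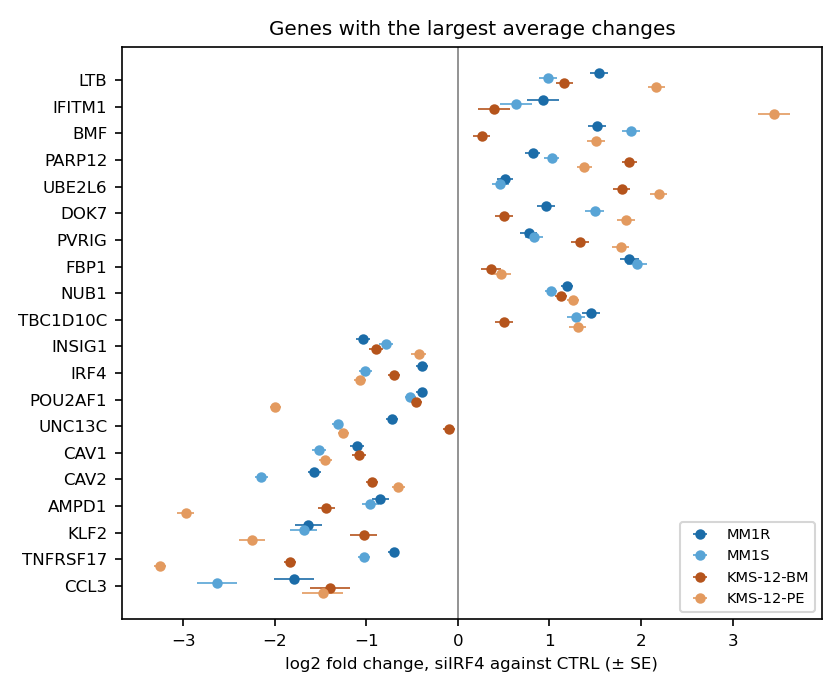
Log2 fold change of siIRF4 against CTRL (horizontal axis, point ± SE from limma) in each line for the 20 genes with the largest average changes under the fixed rule. TNFRSF17 and AMPD1 fell most in KMS-12-PE (-3.26 and -2.97), and IFITM1 rose most there (3.45).

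Of the 35 gene lists, 22 passed the camera test on average with the preset correlation, 8 higher and 14 lower, and 5 with an estimated correlation. Member calls adjusted over the list alone gave the same counts as over all genes, except for 1 B cell gene lower, 11 pro-apoptotic genes higher, 9 immediate early genes lower and 13 hypoxia genes lower. No list that passed the test here changed the sign of its median under median-of-ratios scaling. In the sentences that follow, members are counted out of those tested.

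Cell division genes fell on average, with large falls in the MM1 lines and medians near 0 in the KMS-12 lines. All 38 DNA replication and G1/S genes fell on average (median log2 change -0.37, adjusted p = 2.4e-22, and adjusted p = 0.0564 with an estimated correlation), with CDC45 at -0.63 ± 0.023 and EXO1 at -0.61 ± 0.027. All 42 mitosis and G2/M genes fell on average (median log2 change -0.31, adjusted p = 8.5e-20, and adjusted p = 0.10 with an estimated correlation), among them CKS1B (-0.40) and CCNB1 (-0.33). The G2/M median was -0.71 in MM1R and -0.61 in MM1S, where all 42 genes were lower, against 0.087 in KMS-12-BM and -0.0071 in KMS-12-PE. In KMS-12-BM 4 G2/M genes were higher and 0 lower. Replication-dependent histone genes gave 7 higher and 2 lower of 20 (median log2 change 0.16, adjusted p = 0.36, and adjusted p = 0.74 with an estimated correlation), with HIST1H2AC at 0.92, HIST1H2BK at 0.49, HIST1H1E at -0.89 and HIST1H1B at -0.43.

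Interferon-stimulated genes rose, 27 of 31, and 4 fell (median log2 change 0.38, adjusted p = 3.9e-08, and adjusted p = 0.0461 with an estimated correlation). XAF1 changed by 1.57 ± 0.051 and DTX3L by 1.09 ± 0.042, while SAMD9L (-0.40 ± 0.044) and HERC5 (-0.16 ± 0.040) fell, HERC5 not with a pseudocount of 0.1, which gave 0.0117. XAF1 stood at 0.0255 and 0.112 TPM in KMS-12-BM, where 8 members were higher. Of the other interferon regulatory factors, 6 of 7 rose and 0 fell (median log2 change 0.19, adjusted p = 0.00305, and adjusted p = 0.11 with an estimated correlation), IRF1 by 0.68 ± 0.037 and IRF7 by 0.54 ± 0.038, each in all 4 lines. Of 22 NF-kB target genes 16 rose and 3 fell (median log2 change 0.19, adjusted p = 0.00341, and adjusted p = 0.28 with an estimated correlation), with IL2RG at 0.54, ICAM1 at 0.39 and CCL4, next to CCL3, at -0.61.

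On average, genes of plasma cells fell and genes of earlier B cells rose. Of 19 plasma cell genes 13 fell and 5 rose (median log2 change -0.18, adjusted p = 0.00186, and adjusted p = 0.10 with an estimated correlation). Besides TNFRSF17 and POU2AF1, PRDM1, the regulator of plasma cell fate, changed by -0.54 ± 0.027, ELL2, a secretory elongation factor, by -0.56 ± 0.027, XBP1 by -0.18 ± 0.013, SLAMF7 by -0.55 ± 0.095 and CD38 by -0.28 ± 0.060. The lymphoid transcription factor genes IKZF3 (0.39) and IKZF1 (0.16) rose. TNFRSF13B, at -1.35 in KMS-12-PE, stood there at 1.64 TPM in CTRL against 406 TPM in MM1R. Of 14 B cell genes 10 rose and 0 fell (median log2 change 0.29, adjusted p = 0.00246, and adjusted p = 0.10 with an estimated correlation), with SPIB at 0.83 ± 0.051 and CD79B at 0.47 ± 0.034. MHC class II genes gave 8 higher and 0 lower of 12 (median log2 change 0.12, adjusted p = 0.0219, and adjusted p = 0.16 with an estimated correlation), HLA-DMB at 0.50 and HLA-DMA at 0.26. By line, 6 MHC class II genes rose in MM1R and 11 in KMS-12-PE, 4 fell and 0 rose in MM1S, and 1 rose in KMS-12-BM.

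Genes of protein quality control fell on average by small amounts. All 27 proteasome genes fell (median log2 change -0.20, adjusted p = 3.6e-14, and adjusted p = 0.0461 with an estimated correlation), among them PSMB6 (-0.33) and PSMA2 (-0.27). All 14 heat shock genes fell (median log2 change -0.32, adjusted p = 2.9e-09, and adjusted p = 0.0461 with an estimated correlation), FKBP4 by -0.36 ± 0.016 and HSP90AA1 by -0.40 ± 0.020. Of 26 unfolded protein response and ER chaperone genes 19 fell and 5 rose (median log2 change -0.19, adjusted p = 1.2e-06, and adjusted p = 0.10 with an estimated correlation), with SEL1L at -0.73 ± 0.026, DNAJB11 at -0.36 ± 0.015, EDEM1 at 0.17 and DNAJB9 at 0.12. In MM1R, 9 of these genes rose and 4 fell (median 0.012, adjusted p = 0.42). Of 23 ATF4 and amino acid response genes 17 fell and 1 rose (median log2 change -0.27, adjusted p = 1.3e-07, and adjusted p = 0.0461 with an estimated correlation), with PSAT1 at -0.75, SHMT2 at -0.32 and DDIT4 at 0.98.

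Ribosome biogenesis genes that MYC activates fell, 31 of 32 (median log2 change -0.19, adjusted p = 3.2e-13, and adjusted p = 0.0461 with an estimated correlation), with ODC1 at -0.40 ± 0.018 and TCOF1 at -0.49 ± 0.023. MYC itself had an average change of -0.019 ± 0.022 (adjusted p = 0.47), since it rose in MM1R (0.46) and MM1S (0.23) and fell in KMS-12-BM (-0.47) and KMS-12-PE (-0.29). All 33 cytosolic ribosomal protein genes rose slightly (median log2 change 0.14, adjusted p = 6.8e-10, and adjusted p = 0.16 with an estimated correlation), RPL3 by 0.25 and RPLP0 by 0.18.

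Lipid and glucose metabolism genes fell. Of 24 cholesterol synthesis genes 21 fell and 1 rose (median log2 change -0.30, adjusted p = 2.5e-09, and adjusted p = 0.11 with an estimated correlation), with ACAT2 at -0.49 ± 0.025, EBP at -0.44 ± 0.023 and SQLE at -0.43 ± 0.028, while TM7SF2 rose by 0.26. Of 12 fatty acid synthesis genes 10 fell and 2 rose (median log2 change -0.21, adjusted p = 0.00354, and adjusted p = 0.28 with an estimated correlation), with FADS1 at -0.64, SCD at -0.49, ACACA at -0.30 and ACSS2 at 0.20. The rise of ELOVL6 (0.17) reversed with a pseudocount of 0.1, which gave -0.0202. Of 22 glycolysis genes 14 fell and 5 rose (median log2 change -0.16, adjusted p = 0.00186, and adjusted p = 0.24 with an estimated correlation), with PDK1 at -0.60, LDHA at -0.43, SLC16A3 at 0.29 and ALDOC at 0.20. Hypoxia genes, which include PDK1 and LDHA, gave 11 lower and 4 higher of 19 (median log2 change -0.17, adjusted p = 0.0186, and adjusted p = 0.20 with an estimated correlation), BNIP3L being at 0.54 and KDM3A at 0.37. Of 29 oxidative phosphorylation genes 13 fell and 5 rose (median log2 change -0.036, adjusted p = 0.0915, and adjusted p = 0.30 with an estimated correlation), with ATP5G1 at -0.24, ATP5B at -0.11 and SDHA at 0.15.

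Genes of cell death moved in both directions. Of 18 pro-apoptotic genes 10 rose and 3 fell (median log2 change 0.20, adjusted p = 0.0107, and adjusted p = 0.0674 with an estimated correlation). Besides BMF, BCL2L11, which encodes BIM, rose by 0.57 ± 0.023, BBC3, which encodes PUMA, by 0.66 ± 0.054, the death receptor gene TNFRSF10B by 0.46 ± 0.030 and CASP8 by 0.28 ± 0.020. BAK1, a pore-forming member of the BCL2 family, fell (-0.15 ± 0.023). Of 10 anti-apoptotic genes 7 rose and 2 fell (median log2 change 0.21, adjusted p = 0.11, and adjusted p = 0.51 with an estimated correlation), MCL1 by 0.21 and CFLAR by 0.23, with BIRC5 at -0.25, a gene also of the mitosis list, and BCL2L2 at -0.18. BCL2 rose in MM1R (0.17) and MM1S (0.27) and fell in KMS-12-BM (-0.24) and KMS-12-PE (-0.21). Of 22 p53 target genes 12 rose and 5 fell (median log2 change 0.16, adjusted p = 0.0219, and adjusted p = 0.28 with an estimated correlation), with SESN1 at 0.46, PLK2 at 1.05 although it fell in KMS-12-PE (-0.76), MDM2 at -0.23 and AEN at -0.22, while in KMS-12-PE 8 rose and 10 fell.

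Of 14 genes linked to IRF4 in myeloma, 7 fell and 4 rose (median log2 change -0.15, adjusted p = 0.0555, and adjusted p = 0.39 with an estimated correlation). CDK6 changed by -0.44, HK2 by -0.27 and ZEB1 by 0.23, STAG2 by -0.042 (adjusted p = 0.19) and CASP10 by 0.045 (adjusted p = 0.0910). BCL6 rose in MM1R, from 0.392 to 2.52 TPM, and stood under 0.5 TPM in both KMS-12 lines. MAF-driven genes gave 4 higher and 2 lower of 8 (median log2 change 0.12, adjusted p = 0.42, and adjusted p = 0.74 with an estimated correlation), with DEPTOR at 0.25, CX3CR1 at 1.09, CCND2 at -0.45 and ITGB7 at -0.53. In KMS-12-PE, CCND2 and ITGB7 stood at 1.498 and 61.6 TPM in CTRL, against 183 and 8638 TPM in MM1S. From CTRL to siIRF4 of KMS-12-PE, ITGB7 went from 0.480% to 0.0771% of its MM1 level, and CCND2 from 0.839% to 0.122%. The average falls of both genes therefore include a fall in KMS-12-PE that is open to admixture. Acetyltransferase, acetyl-lysine reader and deacetylase genes, tested as 1 list, gave 8 higher and 3 lower of 19 (median log2 change 0.051, adjusted p = 0.42, and adjusted p = 0.78 with an estimated correlation). In that list the reader gene BRD3 changed by 0.53. The deacetylase genes HDAC1, HDAC2 and HDAC3 changed by 0.15, -0.095 and -0.065. EP300, which encodes p300, changed by 0.068 ± 0.035 (adjusted p = 0.10), and CREBBP by 0.10 ± 0.039 (adjusted p = 0.0329).

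Immediate early genes gave 6 higher and 7 lower of 19 (median log2 change -0.096, adjusted p = 0.67, and adjusted p = 0.83 with an estimated correlation), with BTG2 at 0.66, KLF6 at 0.38, JUN at -0.62 and NR4A1 at -0.60. NRF2 targets gave 9 lower and 3 higher of 17 (median log2 change -0.091, adjusted p = 0.0219, and adjusted p = 0.24 with an estimated correlation), with SRXN1 at -0.37, TXNRD1 at -0.28, HMOX1 at 0.39 and GCLC at 0.13. Lysosome and autophagy genes gave 11 higher and 6 lower of 22 (median log2 change 0.044, adjusted p = 0.21, and adjusted p = 0.65 with an estimated correlation), CTSB at 0.38, ATP6V1H at 0.35 and GLA at -0.60. Glucocorticoid response genes gave 4 higher and 1 lower of 9 (median log2 change 0.058, adjusted p = 0.11, and adjusted p = 0.31 with an estimated correlation), with SGK1 at 0.70 and ZFP36 at -0.11. NR3C1, the glucocorticoid receptor gene, stood at 2.84 TPM in MM1R CTRL and 41.0 TPM in MM1S CTRL.

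Markers of other cell types gave few calls in the MM1 lines and KMS-12-BM. Stromal markers gave 7 lower of 9 on average (median log2 change -0.30, adjusted p = 0.0212, and adjusted p = 0.36 with an estimated correlation), with DCN at -0.36 and COL6A3 at -0.52, and their median was -1.02 in KMS-12-PE. T and NK cell markers gave 6 higher and 1 lower of 9 (median log2 change 0.17, adjusted p = 0.0905, and adjusted p = 0.16 with an estimated correlation), with PRF1 at 0.93, CD7 at 0.87 and TRAT1 at -0.20. Epithelial markers gave 1 higher and 1 lower of 7 (median log2 change -0.11, adjusted p = 0.44, and adjusted p = 0.63 with an estimated correlation), CLDN4 at 0.19 and KRT5 at -0.57. Myeloid markers gave 0 higher and 1 lower of 3 (median log2 change -0.061, adjusted p = 0.51, and adjusted p = 0.72 with an estimated correlation), S100A8 at -0.50, and erythroid markers gave 1 higher and 0 lower of 3 (median log2 change 0.011, adjusted p = 0.99, and adjusted p = 0.99 with an estimated correlation), HBA2 at 0.16. KRT5, S100A8 and DCN were present at 55.8, 62.3 and 31.9 TPM in KMS-12-PE CTRL and at 50.9, 52.7 and 19.2 TPM in MM1S CTRL, and under 0.1 TPM in MM1R and KMS-12-BM. Over both conditions, the stromal genes COL1A1, COL1A2 and COL3A1 stood at 30.6, 12.8 and 10.2 TPM in MM1S. Their levels were 13.2, 8.21 and 7.07 TPM in KMS-12-PE, and at most 0.569 TPM in MM1R and KMS-12-BM. COL6A3 was instead highest in KMS-12-BM (53.8 TPM). Part of the stromal fall may therefore not be of the lines themselves, which was not tested.

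By fry, 31 of the 35 lists moved on balance one way on average, which does not compare a list with other genes. The median and mean of a list differed in sign on average for the erythroid cell markers, and for no other list.

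**Figure D3:**
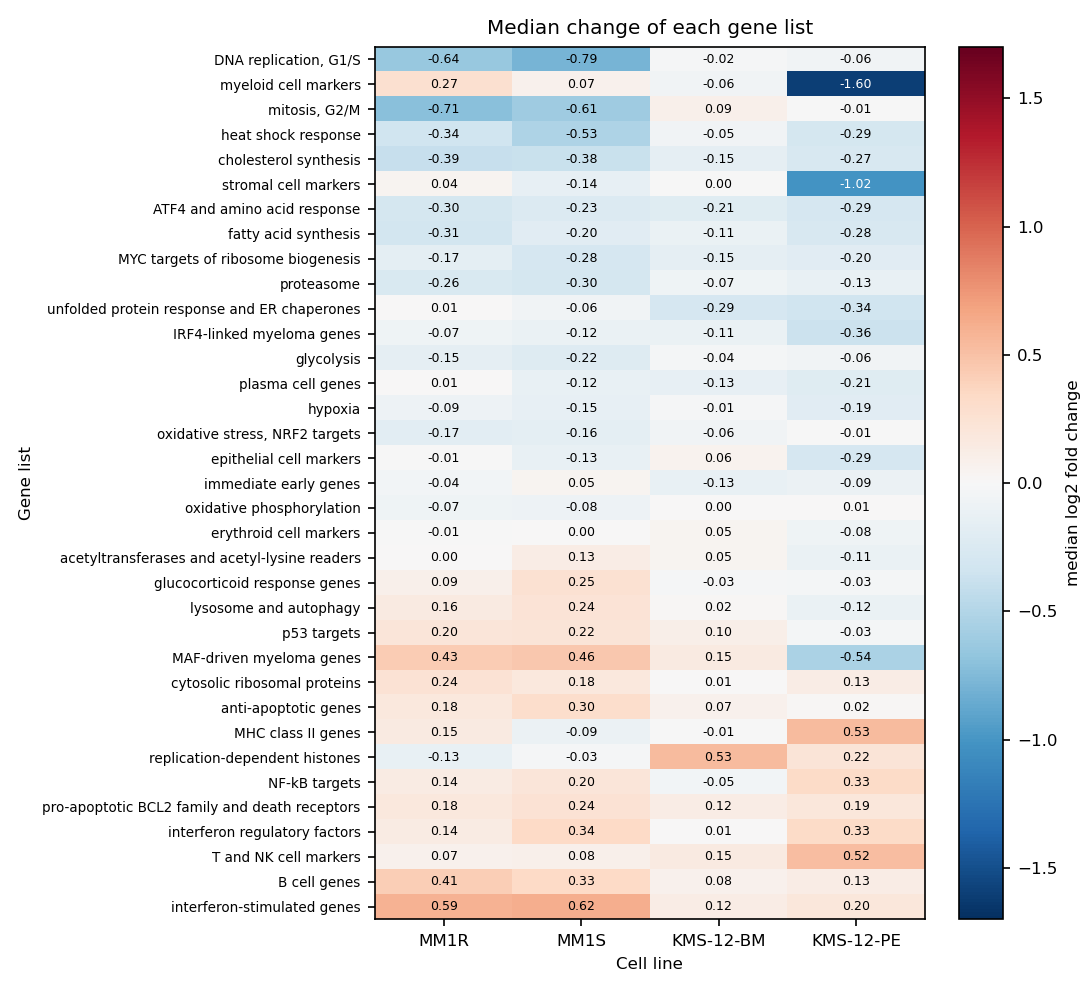
Median log2 fold change of siIRF4 against CTRL over the tested members of each of the 35 lists (vertical axis) in each line (horizontal axis), as colour and number. Cell cycle lists are low in MM1R and MM1S (-0.64 and -0.79 for G1/S) and near 0 in KMS-12-BM and KMS-12-PE.

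In MM1R, siIRF4 raised KRT15 and PLK2 most and lowered the chemokine genes CCL3 and CCL4. KRT15, a keratin gene, rose from 19.6 to 165 TPM (3.01 ± 0.18), PLK2, a p53 target kinase, from 10.4 to 70.4 TPM (2.64 ± 0.099), and CX3CR1, a chemokine receptor, from 32.6 to 171 TPM (2.35 ± 0.16). SCNN1G (2.29) and FRMD3 (2.26) came next. CCL3 (-1.79 ± 0.22), the myeloma surface antigen gene GPRC5D (-1.72 ± 0.20), the retinoic acid hydroxylase gene CYP26A1 (-1.72), KLF2 (-1.63) and CCL4 (-1.62) fell most. In total 6980 genes changed, 3772 higher and 3208 lower, 243 by 1 or more.

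MM1S changed in much the same way. KRT15 (2.93 ± 0.18), FRMD3 (2.35 ± 0.13) and PLK2 (2.17 ± 0.099) rose again, with the interferon-induced genes XAF1 (2.22 ± 0.10) and GBP4 (2.10 ± 0.087). CCL3 went from 360.1 to 57.6 TPM (-2.63 ± 0.22), and CYP26A1 (-2.18 ± 0.13), CAV2 (-2.15), GPRC5D (-2.03) and HRASLS2 (-1.76) also fell. A total of 7596 genes changed, 4405 higher and 3191 lower, 300 by 1 or more. Of the 5540 genes called in both MM1 lines, 99.3% changed in the same direction, and log2 changes correlated across genes at r = 0.722.

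In KMS-12-BM, siIRF4 lowered ER chaperone genes and plasma cell genes. TNFRSF17 went from 308 to 85.8 TPM (-1.84 ± 0.065), TXNDC5, an ER protein disulfide isomerase, from 290.0 to 81.4 TPM (-1.76 ± 0.35), CCL3 changed by -1.40, the fructose transporter gene SLC2A5 by -1.39 and RASGRP3 by -1.09. SMIM24 rose from 7.003 to 32.9 TPM (2.08 ± 0.14), followed by PARP12 (1.87), UBE2L6 (1.79), ISG20 (1.73) and BAI1 (1.73). Of 26 unfolded protein response genes 18 fell and 0 rose (median log2 change -0.29, adjusted p = 9.5e-30, and adjusted p = 0.00177 with an estimated correlation; 21 fell when adjusted over the list alone). Plasma cell genes gave 9 lower and 0 higher of 19 (median log2 change -0.13, adjusted p = 4.4e-09, and adjusted p = 0.00539 with an estimated correlation; 10 lower adjusted over the list alone).

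In total 2650 genes changed in KMS-12-BM, 1730 higher and 920 lower, 49 by 1 or more. Without siIRF4 replicate 1, which held transcripts abundant in MM1 cells at a median of 1.10% of their MM1 level against 0.401% and 0.329% in the other replicates, 1751 genes changed. Leaving out any other KMS-12-BM library gave 2004 to 2675 genes, and a fit without genes open to admixture gave 2564. The share of calls that were higher was 65.3%, and 48.5% with median-of-ratios scaling, so the balance of rises and falls in this line depends on the scaling.

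In KMS-12-PE, siIRF4 raised MHC class II genes and lowered the BCMA gene more than in the other lines. SMIM24 rose from 0.433 to 15.2 TPM (3.49 ± 0.14), IFITM1 from 19.96 to 227 TPM (3.45 ± 0.18), the cytokine gene IL32 from 175 to 843 TPM (2.26 ± 0.25) and the chemokine gene CCL5 from 4.92 to 28.9 TPM (2.34 ± 0.096), with CHRNA2 at 2.46. TNFRSF17 (-3.26 ± 0.065), AMPD1 (-2.97 ± 0.095), TRIM49B (-2.61 ± 0.16) and HRASLS2 (-2.60 ± 0.12) fell most, with UCHL1 (-2.72 ± 0.28), which stood at 8.49 TPM in KMS-12-PE CTRL and at 1485 TPM in MM1S CTRL. MHC class II genes rose, 11 of 12 and 12 adjusted over the list alone (median log2 change 0.53, adjusted p = 1.3e-08, and adjusted p = 0.00739 with an estimated correlation). NF-kB targets rose, 16 of 22 (median log2 change 0.33, adjusted p = 4.8e-07, and adjusted p = 0.0801 with an estimated correlation).

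A total of 5764 genes changed in KMS-12-PE, 2404 higher and 3360 lower, 299 by 1 or more. Of the 5764 genes, 150 were below 2% of their level in an MM1 group in both conditions, and 145 of them were lower. By camera with the preset and the estimated correlation, 17 and 0 lists passed in MM1R, 17 and 4 in MM1S, 13 and 4 in KMS-12-BM, and 20 and 1 in KMS-12-PE.

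Across the 4 lines, 361 genes rose in every line and 293 fell in every line, against 20.02 and 9.17 if the calls of the lines were independent. Independence could not hold, since the lines of a pair share a donor and all lines share the treatment and the fit. The excess alone therefore does not show a common effect of IRF4 loss. A further 1372 genes were called in opposite directions in some lines. KMS-12-BM and KMS-12-PE shared the direction of 86.1% of the 1492 genes called in both, with r = 0.280 across genes. Between an MM1 and a KMS-12 line r lay between 0.220 and 0.240, genes not being independent replicates.

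**Figure D4:**
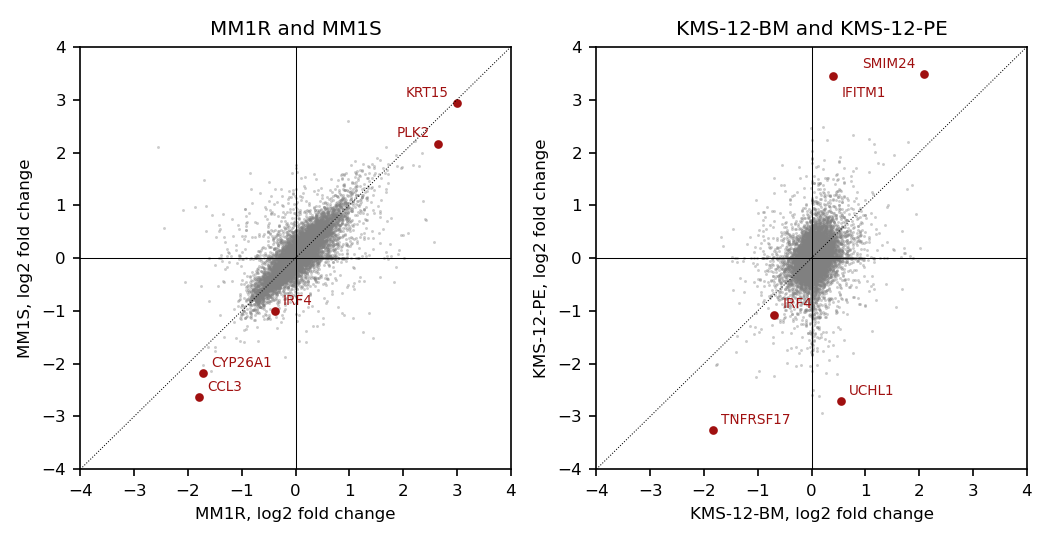
Log2 fold change of siIRF4 against CTRL for each tested gene (grey points) in MM1R and MM1S (left) and in KMS-12-BM and KMS-12-PE (right), with equal change as a dotted line and some named genes in red. The MM1 lines follow each other closely (r = 0.722) and the KMS-12 lines loosely (r = 0.280).

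The difference of effects between MM1R and MM1S asked whether related lines respond alike. S100A9 rose in MM1R, from 24.8 to 94.7 TPM, and its effect exceeded that in MM1S by 1.83 ± 0.35 (adjusted p = 0.00974). S100A9 is also abundant in keratinocytes, whose transcripts were present in MM1S libraries, and it stood at 75.4 and 82.9 TPM in MM1S CTRL and siIRF4. LILRA4 (1.29 ± 0.098) and IFITM3 (1.27 ± 0.29) followed, and TMEM238 (-1.95 ± 0.48), LHX8 (-1.47 ± 0.19) and NRTN (-1.06 ± 0.20) differed in the opposite direction. MHC class II genes, of which 4 fell in MM1S, differed, 6 of 12 with the higher effect in MM1R and 9 adjusted over the list alone (median log2 change 0.37, adjusted p = 4.5e-11, and adjusted p = 0.00166 with an estimated correlation). The fall of IRF4 was smaller in MM1R by 0.62 ± 0.094 (adjusted p = 9.1e-04). In total 374 genes differed, 173 with the higher effect in MM1R. The count was 171 with a pseudocount of 0.1, and 192, 223, 248 and 215 without MM1R siIRF4 replicate 2, MM1R siIRF4 replicate 3, MM1R CTRL replicate 3 or MM1S CTRL replicate 2. IFITM3 and TMEM238 were near the threshold, with adjusted p = 0.0671 for IFITM3 without MM1R CTRL replicate 3 and adjusted p = 0.10 for TMEM238 without MM1R siIRF4 replicate 2, and single other libraries ended these calls too.

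Between KMS-12-BM and KMS-12-PE the effects differed more. IFITM1 (-3.05 ± 0.25), CHRNA2 (-2.46 ± 0.16) and FAM43A (-2.23 ± 0.18) had the higher effect in KMS-12-PE. UCHL1 (3.26 ± 0.39), TRIM49B (2.75 ± 0.22) and PCP4 (2.67 ± 0.49) had the lower effect there and fell there, without a call in KMS-12-BM (0.54, 0.14 and 0.47). UCHL1 and PCP4 are abundant in MM1 cells and stood at 8.49 and 5.59 TPM in KMS-12-PE CTRL, under 2% of their level in MM1S CTRL. Both were also raised in KMS-12-BM siIRF4 replicate 1, UCHL1 at 0.825% of its MM1 level against 0.340% and 0.208% in the other replicates, so their differences are open to admixture in both lines. MHC class II genes had the higher effect in KMS-12-PE, 11 of 12 and 12 adjusted over the list alone (median log2 change -0.50, adjusted p = 3.7e-10, and adjusted p = 0.00262 with an estimated correlation). In total 3476 genes differed, 69.1% of them with the higher effect in KMS-12-BM, or 52.3% with median-of-ratios scaling.

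Between the MM1 pair and the KMS-12 pair the cell cycle set the lines apart. G2/M genes had the lower effect in the MM1 lines, all 42 (median log2 change -0.72, adjusted p = 2.8e-33, and adjusted p = 0.0823 with an estimated correlation), as had all 38 G1/S genes (median log2 change -0.67, adjusted p = 1.1e-31, and adjusted p = 0.0722 with an estimated correlation). Unfolded protein response genes had the lower effect in the KMS-12 lines, 23 of 26 (median log2 change 0.36, adjusted p = 1.3e-11, and adjusted p = 0.0722 with an estimated correlation). KRT15 (3.02 ± 0.18), PLK2 (2.72 ± 0.099) and SCNN1G (2.26 ± 0.16) had the higher effect in the MM1 lines, with no rise called in a KMS-12 line, while SMIM24 (-2.64 ± 0.14), the retinoid gene CYP26A1 (-1.93 ± 0.13) and the HES family gene HES6 (-1.69 ± 0.096) had the lower effect there. MYC differed by 0.73 ± 0.044 (adjusted p = 5.5e-11). In total 6792 genes differed, 3771 with the higher effect in the MM1 pair.

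At baseline, the MM1 lines differed in the cancer-testis gene CTAG2 and the lymphoid gene PTPRCAP. In CTRL cells CTAG2 stood at 149 TPM in MM1R and 1.56 TPM in MM1S, PTPRCAP at 148 and 1.32 TPM, and the cell cycle inhibitor gene CDKN2A at 115 and 2.73 TPM. TKTL1 (5.68) and MAGEA6 (5.00) were also higher in MM1R. KRT5, KRT14, KRT6A, PI3 and S100A8, which are abundant in skin keratinocytes, were listed at under 0.1 TPM in MM1R and at 33.2 to 52.7 TPM in MM1S. A total of 8653 genes differed, 716 by 1 or more, with 51.8% higher in MM1R, or 46.3% with median-of-ratios scaling. The labels give no run or batch, and low levels of foreign transcripts part MM1R and KMS-12-BM from MM1S and KMS-12-PE, so a difference of processing would be confounded with the comparisons of MM1R with MM1S and of KMS-12-BM with KMS-12-PE.

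KMS-12-BM and KMS-12-PE differed more at baseline. The B cell surface genes CD27 (267 against 0.272 TPM) and CD37 (282 against 0.838 TPM) were higher in KMS-12-BM, as were ACTL8 (7.94), PCSK1N (7.51) and CDA (6.92). IGLL1 (-9.43), the cancer-testis genes PAGE5 (-8.64) and MAGEB2 (-7.36), the metallothionein gene MT1E (-7.18) and SMOC1 (-7.15) were higher in KMS-12-PE. A total of 11677 genes differed, 3988 by 1 or more, with 48.3% higher in KMS-12-BM, or 50.1% with median-of-ratios scaling. CCND1 was high in both KMS-12 lines, at 620.4 and 497 TPM, and MAF in both MM1 lines, at 438 and 368 TPM.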

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

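All counts from regrouped libraries and all tests of explanations in this part were chosen after the results were seen. Each result in the next 3 paragraphs stands here because the effect of siIRF4 differed between cell lines by a test of the difference itself.

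Between MM1R and MM1S, 374 genes differed, and chance regrouping of the libraries can be excluded, since the highest of 99 other splits gave 6. For lists the count was 14, and 2 of 100 splits, the real one included, gave as many (highest other 14). A regrouped count equal to the real one does not exclude chance for the lists, and 1 of these lists passed with an estimated correlation. MHC class II genes had a median difference of 0.37. The differences were 1.83 for S100A9, 1.29 for LILRA4, 1.27 for IFITM3, -1.95 for TMEM238, -1.47 for LHX8, -1.06 for NRTN, 0.62 for IRF4 and 0.24 for MYC. S100A9 is one of the listed keratinocyte genes and stood at 75.4 TPM in MM1S CTRL and 24.8 TPM in MM1R CTRL.

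Between KMS-12-BM and KMS-12-PE, 3476 genes differed, against at most 538 in 99 other splits, so chance regrouping can be excluded for the genes. For the 11 lists it cannot, since 21 of 100 splits gave as many (highest other 20), and 1 passed with an estimated correlation. MHC class II genes had a median difference of -0.50. The differences were -3.05 for IFITM1, -2.46 for CHRNA2, -2.23 for FAM43A, 3.26 for UCHL1, 2.75 for TRIM49B, 2.67 for PCP4, 2.26 for MAF, 1.62 for CCND2, 0.37 for IRF4 and -0.18 for MYC.

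Between the MM1 pair and the KMS-12 pair, 6792 genes differed, and the highest of 99 other splits gave 6056. As for the other differences between lines, the regrouped residuals came from a fit without the difference, so they still carried it. A split that kept most libraries in place kept much of it. The count of 6056 is therefore no clean measure of chance, and the small gap does not exclude chance regrouping for these genes. For the 17 lists chance regrouping cannot be excluded, since 5 of 100 splits gave as many (highest other 20), and 0 passed with an estimated correlation. The differences were 3.02 for KRT15, 2.72 for PLK2, 2.26 for SCNN1G, -2.64 for SMIM24, -1.93 for CYP26A1, -1.69 for HES6, 0.73 for MYC and 0.19 for IRF4. For fixed genes of myeloma they were 1.62 for MAF, -0.47 for CCND2, -0.26 for NR3C1, 0.26 for EP300 and 0.29 for CREBBP.

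On average over the lines, 9014 genes changed, against at most 1413 in 99 other splits, and 22 lists passed, against at most 21, with 1 of 100 splits, the real one, as large in each case. Chance regrouping can be excluded for the genes. For the lists it cannot on this count, since the preset camera test passed nearly as many lists in a regrouped set. Within a line, the 10 splits of 6 libraries are too few for a share under 0.05. The real and highest other counts of genes were 6980 and 27 in MM1R, 7596 and 3 in MM1S, 2650 and 8 in KMS-12-BM, 5764 and 2 in KMS-12-PE, 8653 and 1 between CTRL of MM1R and MM1S, and 11677 and 2 between CTRL of KMS-12-BM and KMS-12-PE. For lists they were 17 and 14 in MM1R, 17 and 19 in MM1S, 13 and 13 in KMS-12-BM, and 20 and 16 in KMS-12-PE. As many lists as the real split came from 3 of 10 splits in MM1S and 3 of 10 in KMS-12-BM.

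Transcripts abundant in MM1 cells appeared at low levels in KMS-12 libraries. In KMS-12-BM siIRF4 replicate 1, all 13 genes low in KMS-12-BM CTRL stood above the other siIRF4 replicates, by a median log2 of 1.59 (SD 0.291), as reads or RNA of an MM1 line would give. An effect of siIRF4 on these genes is argued against, since the other siIRF4 replicates stood at a median of 0.14 over CTRL. In KMS-12-PE CTRL, 22 genes abundant in MM1 and below 2% of that level in KMS-12-PE stood at a median of 0.789% of it, with an SD of log2 shares of 0.487 against 1.24 for 19 genes abundant in KMS-12-BM and chosen alike, as a small share of MM1 reads could give. Of these genes 19 were lower in siIRF4 by value (median -2.65). The others were not, among them CCR1 (0.779% and 1.04%). An effect on own expression therefore cannot be told apart from MM1 reads for the falls of UCHL1, PCP4, MAF, CCND2, ITGB7 and TNFRSF13B.

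Genes called in both MM1R and MM1S changed by nearly equal amounts in the median, although IRF4 fell less in MM1R. The 1726 genes used were called in both lines and had a mean log2 change over these lines of at least 0.5 in size. Their median ratio of MM1S to MM1R changes was 1.09 (quartiles 0.906 and 1.30), against 2.60 ± 0.477 for IRF4 (SE). For these genes, log2 changes in proportion to the measured log2 change of IRF4 mRNA are argued against by this gap. Needing a call in MM1R left out genes with a small change there, which lowers the ratio by an amount not tested. Delivery of siRNA as such, electroporation and time, which every siIRF4 library shares, cannot be told apart from the loss of IRF4. The fall of heat shock genes (median -0.32) decides nothing here. IRF4 protein was not measured here, so a threshold in IRF4 protein stays untested.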

How the results depend on the processing

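Voom on recovered reads, removal of genes open to admixture and camera with an estimated correlation were added after the data were seen. Of 7933 values for named genes under an alternative, 7815 kept their side of the threshold, and their direction where called. Another 100 lost their call, 14 gained one and 4 reversed. A change of sign in a value called in neither fit was counted as kept. Of the 7815, 5722 came from leaving out 1 library, which for a single line was often a library outside the comparison. Many of these genes were named for being called, so such agreement was likely in advance. The reversed values were ELOVL6 at -0.0202 with a pseudocount of 0.1 and -0.172 with voom, and HERC5 at 0.0117 and 0.162; the cause was not tested. The 374 genes that differ between MM1R and MM1S became 171 with a pseudocount of 0.1, 567 with voom, 243 with separate fits and 192 to 441 leaving out 1 library, and the cause was not tested. In KMS-12-BM, leaving out 1 library gave 1751 to 2812 genes. Camera with an estimated correlation passed 5 lists on average. It passed 0 to 4 lists in single lines and 0 or 1 for the differences between lines. All other totals of genes called in a comparison, and the average count of lists under the other alternatives, stayed within 1.5 times of their value. This did not hold for higher and lower genes counted apart, as the 920 lower genes in KMS-12-BM became 1471 with median-of-ratios scaling. Genes shared between lines and genes changed by 1 or more were not counted under the alternatives.

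With a replicate block, 183 genes differed between MM1R and MM1S, and no other total moved by over 1.5 times. The replicate numbers did not pair the libraries, since correlations of same-numbered siIRF4 and CTRL libraries lay between -0.0878 and 0.0861, and 2 of 12 correlated best with their own number. At 17.3 M reads, the depth limits what can be said of genes near 1 TPM.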

Other observations

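The test of the hypothesis in the last paragraph was chosen after its result was seen, and the genes of the next paragraph were chosen after their values were seen.

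Of genes of surface antigens and chemokines that the labels do not group, some moved the same way in all 4 lines and others were called in only some. The differences of effects between lines are not given here for SLAMF7 and CD38. A call in some lines and not in others therefore does not show that their effects differ. TNFRSF17 fell in all 4 lines, from 857 to 526 TPM in MM1R, 489.9 to 239 TPM in MM1S, 308 to 85.8 TPM in KMS-12-BM and 193 to 19.3 TPM in KMS-12-PE. SLAMF7, an antibody target in myeloma, fell in MM1R (-0.50), MM1S (-0.86) and KMS-12-PE (-1.12), and stood at 1.76 and 2.57 TPM in KMS-12-BM. Its KMS-12-BM level is open to admixture, at 0.970% of its MM1 level in siIRF4 replicate 1 against 0.330% and 0.349% in the other siIRF4 replicates. CD38, another antibody target, fell in MM1S (-0.30) and KMS-12-BM (-0.67), with 0.051 ± 0.12 in MM1R and -0.21 ± 0.12 in KMS-12-PE. The chemokine gene CCL5 rose in MM1R (0.49), MM1S (0.40), KMS-12-BM (0.76) and KMS-12-PE (2.34), while CCL3 fell in these lines (-1.79, -2.63, -1.40 and -1.48).

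Transcripts abundant in KMS-12 lines were also found in MM1 libraries. The lowest share among 1768 genes abundant in KMS-12-BM was 0.531%, 0.568% and 0.507% of their KMS-12-BM level in MM1R siIRF4 replicate 1, siIRF4 replicate 2 and CTRL replicate 3, and 0.0824% to 0.162% in the other MM1R libraries. For 1807 genes abundant in KMS-12-PE it was 0.0582% to 0.324% in MM1S and 0% in MM1R.

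A hypothesis is that keratinocyte transcripts in MM1S and KMS-12-PE libraries come from a source outside the lines. Over 13 such genes the log2 ratio of KMS-12-PE CTRL to MM1S CTRL had an SD of 0.286, against 3.03 over 90 other genes chosen alike, as a shared source would give, and 91.2% of their variance followed one factor per library. Expression by the lines themselves, lowered by siIRF4 in KMS-12-PE, cannot be told apart by the median change of -1.68 there. In MM1S the median change was -0.31, and 0.028 without siIRF4 replicate 3, whose geometric mean over these genes was 7.69 TPM against 25.1 and 23.999 TPM in the other siIRF4 and 19.5 to 31.4 TPM in the CTRL replicates. Values of S100A8, KRT5 and the other genes tested may therefore not be of the line in MM1S and KMS-12-PE. Stromal genes such as DCN and COL1A1, also found mainly in these lines, were not among the 13 genes, so their source was not tested.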
